A study of Mus musculus with 6 samples.

How the data were processed

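Total RNA enriched for small RNA was extracted from sorted mammary cells of virgin wild-type mice, labelled with Cy3 and hybridised to Agilent mouse miRNA arrays, per the labels' protocols. The 6 arrays form 2 groups from the sample titles, P4 (high CD29, enriched for stem cells) and P5 (low CD29, enriched for luminal cells), with 3 arrays each. Nothing in the labels says whether the replicates came from separate animals or sorts, so p-values measure the spread between these samples, which may be technical. All 6 arrays lay on 1 slide and were scanned in 1 scan. The P4 arrays and P5 replicate 1 were in the first row of the slide and the other P5 arrays in the second row.

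The deposited scanner files hold spot intensity on a linear scale, written by Agilent Feature Extraction 11.0.1.1, per the file headers; the submitters' processing notes name version 11.0. The processed signal in these files is background-subtracted and can be negative, and no scaling between arrays had been applied to it. The authors' deposited series matrix holds log2 values. Set against the scanner values, each of its columns equals the log2 of Agilent's summed signal per miRNA plus 1 shift per array and 1 constant per row, within 7.86e-06. The origin of the row constants is unknown, so the centring of these values is only partly settled; their scale and direction follow the scanner values. The medians of its columns were 0.42, -0.36 and -0.06 for P4 and -0.56, -0.47 and 0.06 for P5.

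From the scanner files, spots flagged as outliers and control spots were left out, and the processed signal was averaged per probe and then over the probes of a miRNA. Each array was divided by its 75th percentile over the miRNAs detected on all 6 arrays. Values were then floored and log2 was taken. Detection is Agilent's flag per miRNA. The floor planned before the data were examined, the median signal of undetected miRNAs, was negative (-0.00435 of the scaling signal) and has no log. It was replaced, after this was seen, by the median over arrays of the 95th percentile of undetected signal, 0.0223 or -5.49 on the log2 scale. The miRNAs tested were the 370 detected on all 3 arrays of at least 1 group. Where a miRNA was detected on no array of a group, its fold is given as at least the mean of the bright group over the mean, in the dim group, of the highest of the floor, the lowest detected signal of the array and its own signal. This bound is a ratio of means, so it leaves out the spread between arrays, and it depends on the background correction. No spot was saturated. Of the 103 called miRNAs 101 had more than 1 probe above the floor, and in 2 of them, miR-762 and miR-5103, a probe went the other way.

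P4 was compared with P5 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 2-sided, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists of miRNAs with at least 3 tested members, 19 in all, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it. Of the 10 lists called with the preset correlation, 0 held with an estimated correlation. The lowest adjusted p there was 0.183, for fibroblasts and other mesenchyme. The estimated correlation of that list was negative (-0.115), yet its unadjusted camera p went from 7.42e-06 to 0.00961. The loss of calls can thus reflect more than correlation within lists. How large a shift a list needs to pass there was not tested. The tests, the lists, the alternatives and the rule for named miRNAs were fixed before the data were examined. The rule took the 10 largest differences in each direction among called miRNAs whose groups did not overlap, up to 3 called members of each list (or 2 of the highest signal where none was called), and a set of candidates. Of 237 list members 233 matched a name on the array. miR-145 of the lists was matched to the array's later name miR-145a, which the rule for names did not foresee. No probe was given a genome position: the file headers name the mouse build mm9, and the gene table at hand is of GRCm38.p6 and was used only to find miRNA genes that neighbour each other.

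The calling steps were tested on simulated data with the means and spreads of the 370 miRNAs, in 50 simulations with 20 miRNAs changed per size. A log2 change of 0.5 was recovered in 20.4% of cases, a change of 1 in 73.8% and a change of 2 in 96%, and 3.89% of the calls were false. The simulated miRNAs varied independently and had no floor, unlike the measured ones, so these rates may not hold for the measured data. The alternatives were other scalings, Agilent's summed signal, normexp background correction, the authors' processed values, other averaging over probes, other filters and floors, another eBayes setting, a replicate block, and leaving out each array. normexp used the median spot signal and the median background, in place of the planned mean spot signal, with an offset of 50. The slide could not be fitted as a block, since there was 1, and the array row on it was added as a block after the data were seen, as was a floor at the highest of the arrays' percentiles. Arrays of 1 group correlated at 0.975 to 0.991 (Pearson, across tested miRNAs, which are not independent) and arrays of different groups at 0.877 to 0.903.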

Results

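MicroRNA levels were measured in sorted cells of the mammary gland from virgin wild-type FVB mice, on single-colour microarrays. The sort parted lineage-negative, CD24-positive cells by their level of CD29 (integrin beta 1). The population with high CD29, named P4, is enriched for mammary stem cells per the labels and also holds the basal, myoepithelial layer as background knowledge of this gate. The population with low CD29, named P5, is enriched for luminal cells. Each population had 3 arrays, and the design asked how the 2 populations differ. Each array carried probes for 1247 mouse miRNAs, read from 49880 spots. The P4 arrays detected 325, 384 and 368 miRNAs and the P5 arrays 416, 419 and 367. The means were 359 ± 30.5 and 401 ± 29.2 (SD, n = 3 each), a difference of -58.5 to -24.7 without each array in turn. A 2-sided exact permutation test gave p = 0.3, where 0.1 is the smallest that 3 against 3 allows, so it cannot settle whether the groups differ. The scaling signal of each array, the 75th percentile of commonly detected miRNAs, was 186, 382 and 273 intensity units in P4 and 526, 457 and 315 in P5 (exact permutation p = 0.2). Of the miRNAs on the array, 293 were detected on all 6 arrays and 772 on none. The number of arrays limits the precision of every value below.

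miR-143-3p and miR-145a-5p, partners in 1 cluster known for its high level in smooth muscle and other contractile cells, were 32.3-fold and 29.8-fold higher in P4 (log2 difference 5.01 ± 0.24 and 4.90 ± 0.24, SE, n = 3 arrays each). miR-204-5p and its close relative miR-211-5p were detected on all 3 P4 arrays and on no P5 array, and were at least 56.3-fold and at least 23.2-fold higher in P4. In the other direction, miR-148a-3p was 12.4-fold higher in P5 (log2 difference -3.64 ± 0.21), and miR-34a-5p, a miRNA known as a target of p53, was 9.22-fold higher in P5 (-3.20 ± 0.31), with detection on 2 of the 3 P4 arrays. The groups did not overlap in any of these miRNAs. Sizes of miRNAs with little signal in 1 group depend on the background. With normexp miR-204-5p was at 2.76, miR-211-5p at 1.79 and miR-34a-5p at -1.24. With the authors' processed values the first 2 were at 11.7 and 10.4. The offset of 50 used with normexp shrinks differences between weak signals. The authors' processed values were used without the floor set here. In the summed signal they rest on, undetected spike-in control probes stood at 0.1 intensity units. If undetected miRNAs stood there too, sizes from these values are distances to a set number and not to a measured level.

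Of 370 miRNAs tested, 51 were higher and 52 lower in P4 at an adjusted p under 0.05 with limma, and 37 and 29 of these differed by a log2 value of at least 1. All 103 had groups that did not overlap, as had 156 of the tested miRNAs, where chance gives 10%. Of the higher miRNAs 9 were detected on no P5 array, and of the lower miRNAs 8 were detected on no P4 array. The split between the directions moved with the processing. It was 51 higher and 52 lower in the values reported here, 47 and 77 when scaled over all miRNAs, and 23 and 77 with no scaling. It was 31 and 81 with the authors' processed values, which differ in more than the scaling: they rest on the summed signal, without the floor used here. With normexp background correction it was 49 and 25. These settings shifted the median log2 difference of the tested miRNAs from 0.0013 to -0.17, -0.64, -0.43 and 0.26, and quantile normalization to -0.13, so each difference is relative to that of the other miRNAs. With no filter, where all 1247 miRNAs were tested, 25 were higher and 22 lower. The differences themselves stayed the same. The 772 miRNAs detected on no array then also entered the variance that eBayes shares across miRNAs. Calls lost there can thus reflect more than the larger number of tests. With the array row on the slide as a block, a term chosen after the data were seen, 29 were higher and 23 lower; only the first row held both populations, with P5 replicate 1 as its 1 P5 array, so this fit compares the 3 P4 arrays with that array alone. Of 52 called miRNAs followed across the settings, mostly those named below, 26 lost their call with no filter, 19 with this block, 11 with no scaling, 10 with the authors' processed values and 8 with normexp.

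**Figure D1:**
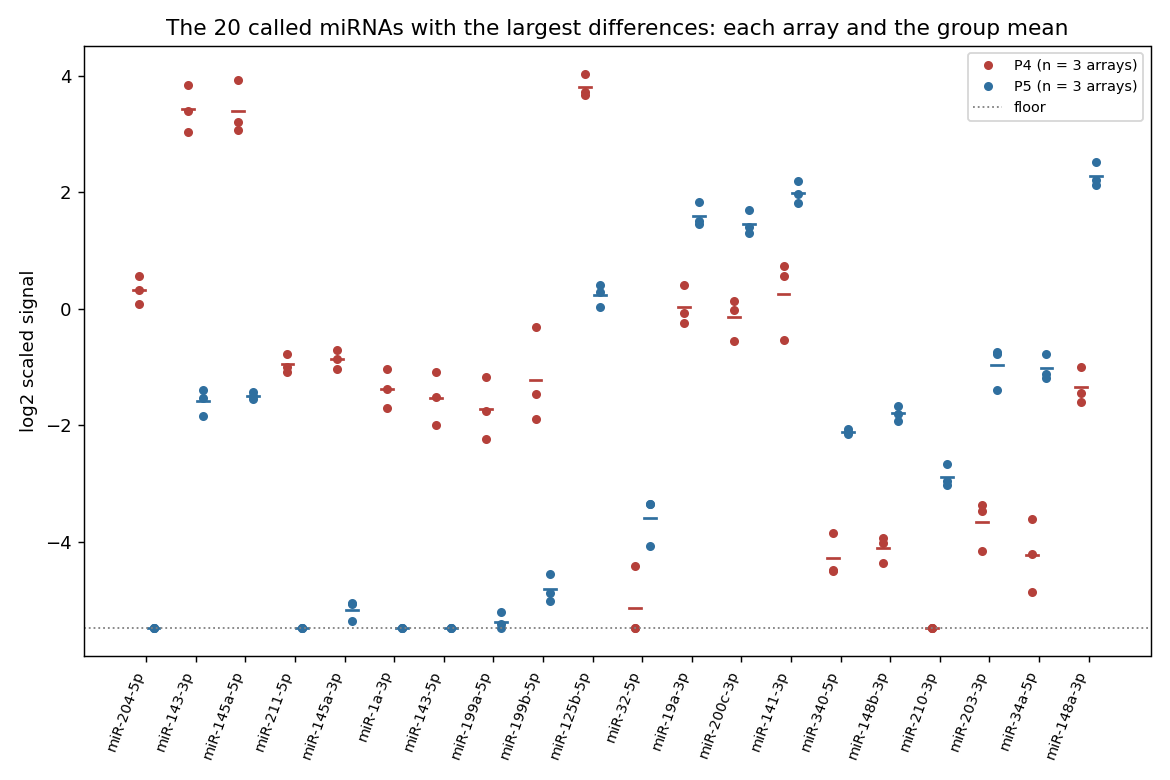
Log2 scaled signal (vertical axis) of the called miRNAs with the largest differences, 10 in each direction, as points for the 3 P4 and 3 P5 arrays with a bar at each group mean; the dotted line is the floor at -5.49. The groups do not overlap for any of the miRNAs, and miR-204-5p, miR-211-5p, miR-1a-3p and miR-143-5p lie at the floor in P5 and miR-210-3p in P4.

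All 4 tested members of the cluster of miR-143 and miR-145 rose in P4 relative to P5. miR-145a-3p differed by 4.30 ± 0.17 on the log2 scale, and miR-143-5p, detected on no P5 array, was at least 15.5-fold higher; with normexp these were 1.80 and 1.43, and the median of the list 3.05 in place of 4.60. As a list they passed camera (adjusted p = 4.7e-05), but not with an estimated correlation (adjusted p = 0.348 with an estimated correlation). The 3 measured members of the clusters of miR-199 and miR-214 were also higher in P4, miR-199a-3p by 3.52 ± 0.38, miR-199b-5p by 3.60 ± 0.39 and miR-199a-5p by 3.65 (adjusted p = 0.000399, 0.000411 and 6.24e-05), and the list passed camera (adjusted p = 0.00391; adjusted p = 0.348 with an estimated correlation). In P5 miR-199b-5p was detected on 2 of the 3 arrays and miR-199a-5p on 1, where the last lay at or near the floor, so its size is uncertain: it was 1.32 with normexp and 7.71 with the authors' processed values. With normexp miR-199a-3p was at 2.22 and miR-199b-5p at 1.62. miR-214-3p, encoded on the same transcript as miR-199a in mammals, was detected on no array. The miR-99, miR-100 and miR-125 clusters had 3 of 5 members higher, led by miR-125b-5p (3.57 ± 0.18, 11.9-fold), with miR-100-5p at 1.58 ± 0.16 and miR-99a-5p at 1.57 ± 0.16; 4 passed when adjusted over the list alone (camera adjusted p = 0.00268; adjusted p = 0.348 with an estimated correlation). All 5 members of the miR-23, miR-27 and miR-24 clusters were higher, among them miR-23b-3p by 1.40 ± 0.21 and miR-24-3p by 1.34 ± 0.19 (camera adjusted p = 0.00546; adjusted p = 0.418 with an estimated correlation). Both tested members of the cluster of miR-221 and miR-222 were higher, miR-222-3p by 2.60 ± 0.26 (1.49 with normexp) and miR-221-3p by 2.27 ± 0.17. With no scaling, miR-23b-3p, miR-27b-3p, miR-24-3p, miR-99a-5p and miR-100-5p kept their direction and did not pass the threshold (0.74, 0.44, 0.69, 0.92 and 0.93), and the medians of their lists were 0.44 and 0.92. Nor did miR-23b-3p and miR-27b-3p pass with the array row as a block (1.31 and 0.998, adjusted p = 0.0532 and 0.0951), or miR-199b-5p with the authors' processed values (5.35, adjusted p = 0.096). With no filter miR-23b-3p, miR-27b-3p and miR-24-3p did not pass (adjusted p = 0.0522 to 0.0891).

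The list of stratified and basal epithelium went both ways and was not called (camera adjusted p = 0.56). miR-205-5p, known from basal and stratified epithelia, was 7.37-fold higher in P4 (2.88 ± 0.28, adjusted p = 0.000298). miR-203-3p, known for its rise in differentiating epidermis, was 6.48-fold higher in P5 (-2.70 ± 0.28, adjusted p = 0.000321; -1.17 with normexp). miR-31-5p (0.62 ± 0.27) and miR-31-3p (0.37 ± 0.24) did not pass the threshold. With no scaling the median of this list turned to -0.16.

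All 6 tested members of the miR-200 family, known to repress the transcription factors Zeb1 and Zeb2, were lower in P4. miR-141-3p differed by -1.74 ± 0.34, miR-200c-3p by -1.61 ± 0.22 and miR-200b-3p by -1.33 ± 0.21, and the median of the family was -1.25 (camera adjusted p = 0.000797; adjusted p = 0.348 with an estimated correlation). With no filter none of these 3 passed (adjusted p = 0.167, 0.0534 and 0.0686). With no scaling the median of the family was -1.90 and that of the cluster of miR-17 to miR-92a, given next, -1.80. The tested 3p arms of the family were detected on all 3 P4 arrays. miR-200b-3p had a mean log2 scaled signal of 1.61 ± 0.31 in P4 (SD, n = 3) against 2.94 ± 0.20 in P5. miR-141-5p was detected on no P4 array, so its difference of -1.12 is a bound set by the floor. Among the P4 arrays the mean of the family lay lowest on replicate 3, at -0.39 from the P4 mean. On that array the means of the endothelial and leukocyte markers given below lay highest, at 0.82 and 0.59. Of the 10 tested members of the cluster of miR-17 to miR-92a and its paralogues, known to promote proliferation, 9 were lower in P4 and 10 passed when adjusted over the list alone (camera adjusted p = 4.7e-05; adjusted p = 0.348 with an estimated correlation). Examples were miR-19a-3p (-1.57 ± 0.21), miR-20b-5p (-1.37 ± 0.22) and miR-18a-5p (-1.46 ± 0.34), the last of which did not pass with normexp (-0.52, adjusted p = 0.0612), without P5 replicate 2 (-1.17, adjusted p = 0.0527) or with detection on 1 array as the filter (adjusted p = 0.0598). The miR-30 family had 2 of 5 members lower, miR-30a-5p (-0.997 ± 0.16, and -1.65 with no scaling) and miR-30b-5p (-0.69 ± 0.18, and -1.34 with no scaling), and all 5 passed when adjusted over the list alone (camera adjusted p = 0.0213; adjusted p = 0.455 with an estimated correlation). Its call was lost with quantile normalization, no scaling or the authors' processed values (median -0.53, -1.15 and -0.82) and without P4 replicate 3 (-0.47, adjusted p = 0.0578) and that of miR-30b-5p without P4 replicates 1 or 2 or P5 replicates 1 or 3 (-0.60 to -0.71, adjusted p = 0.0594 to 0.0902) or with quantile normalization (-0.62, adjusted p = 0.0606). With no filter miR-19a-3p, miR-20b-5p, miR-18a-5p and miR-30b-5p did not pass (adjusted p = 0.0522 to 0.272). With the array row as a block miR-141-3p (-1.94, adjusted p = 0.0705), miR-20b-5p (-1.15, adjusted p = 0.0798), miR-18a-5p (-1.15, adjusted p = 0.193) and miR-30b-5p (-0.82, adjusted p = 0.108) did not pass.

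miRNAs associated with luminal and hormone-sensing epithelium were mostly below detection. Of the 6 on the array 4 were detected on no array, among them miR-375-3p. miR-148a-3p was lower in P4, as given above, and miR-342-3p was higher (0.83 ± 0.18, adjusted p = 0.0112), but did not pass with no scaling, normexp or the authors' processed values (0.17, 0.52 and 0.50), or with no filter (adjusted p = 0.112). Both tested members of the family of miR-34 and miR-449 were lower in P4, with miR-34b-5p at -0.80 ± 0.18 (-1.45 with no scaling) beside miR-34a-5p. miR-34b-5p did not pass with normexp (-0.0124, adjusted p = 0.971), the array row as a block (-0.67, adjusted p = 0.159) or no filter (adjusted p = 0.123), nor miR-34a-5p with the authors' processed values (-5.41, adjusted p = 0.0957). miR-148b-3p (-2.31 ± 0.17) and miR-340-5p (-2.18 ± 0.21) were also lower in P4. The size of miR-148b-3p is uncertain, at -0.67 with normexp and at -2.65 and -0.94 by its 2 probes, and miR-340-5p, detected on 1 of the 3 P4 arrays, did not pass with normexp (-0.50, adjusted p = 0.0677) or the authors' processed values (-6.68, adjusted p = 0.0638). miR-210-3p, known as a target of hypoxia signalling, was detected on all 3 P5 arrays and on no P4 array and was at least 6.06-fold higher in P5; with normexp it did not pass (-0.30, adjusted p = 0.281), and it was at -8.45 with the authors' processed values. miR-32-5p differed by -1.54 (adjusted p = 0.0136), a size set by the floor, as it was detected on 1 of the 3 P4 arrays. With normexp it turned to 0.0462 (adjusted p = 0.874). Its call was also lost with the authors' processed values (-5.39, adjusted p = 0.088), with no filter (adjusted p = 0.248) and with detection on 1 array as the filter (adjusted p = 0.0545). So it was without P5 replicate 1 (-1.42, adjusted p = 0.067) or 2 (-1.42, adjusted p = 0.0608) and with the array row as a block (-1.78, adjusted p = 0.0953).

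**Figure D2:**
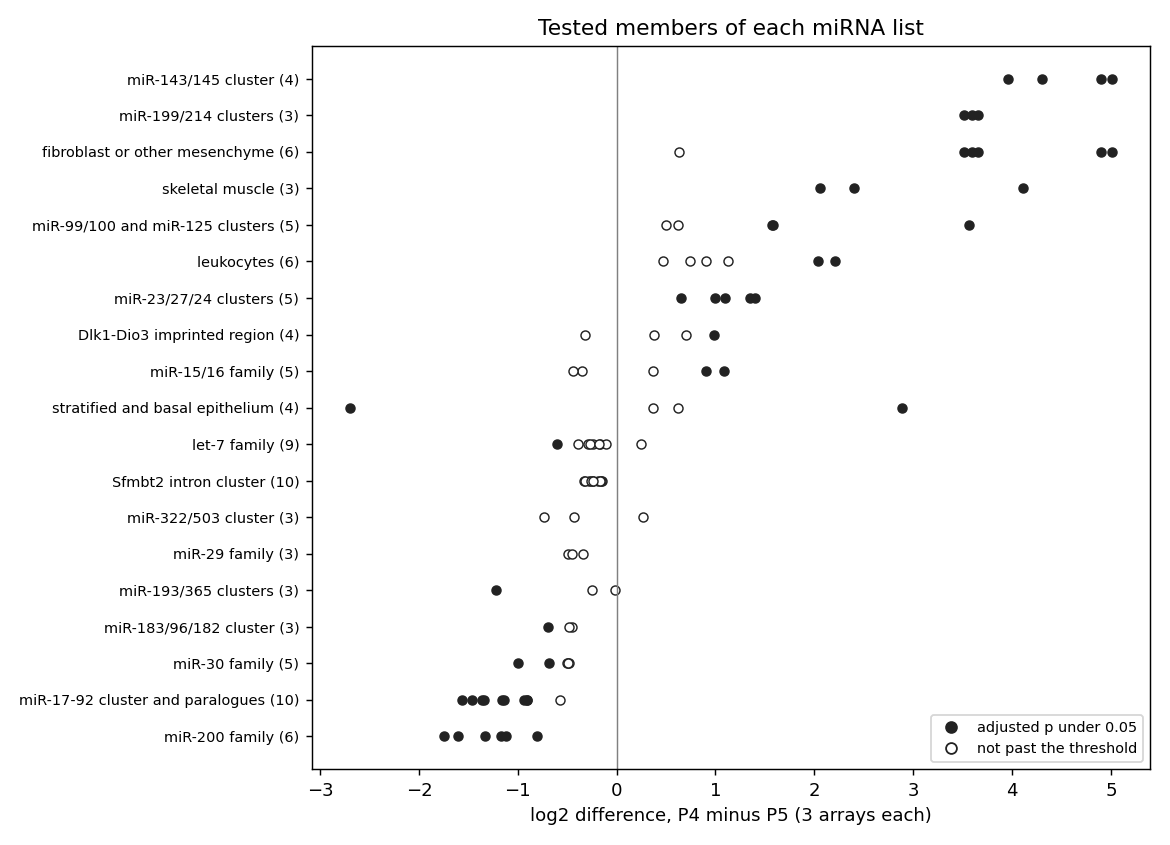
Log2 difference between P4 and P5 (horizontal axis) of each tested member of the 19 lists with at least 3 tested members (vertical axis, number of members in brackets); filled points passed an adjusted p of 0.05 and open points did not. The 4 members of the cluster of miR-143 and miR-145 lie between 3.96 and 5.01 and the 6 of the miR-200 family between -1.74 and -0.80; the 3.96 is a lower bound, for miR-143-5p.

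Markers of other cell types also moved with P4. Both arms of miR-126, a miRNA of endothelial cells, were higher in P4, miR-126-3p by 2.96 ± 0.50 and miR-126-5p by 2.88 ± 0.50 (adjusted p = 0.00409 and 0.00432). With the array row as a block, against P5 replicate 1 alone, the P5 array highest in both arms, these were 2.34 and 2.25, and neither passed the threshold (adjusted p = 0.101 and 0.104). With no filter neither arm passed (adjusted p = 0.146 and 0.150). The leukocyte list had 2 of 6 members higher, miR-150-5p (2.20 ± 0.39; 1.24 with normexp) and miR-146a-5p (2.03 ± 0.20; 0.66 with normexp), and 3 when adjusted over the list alone (camera adjusted p = 0.024; adjusted p = 0.348 with an estimated correlation). Neither passed throughout: miR-150-5p was lost with the array row as a block (2.32, adjusted p = 0.066) and with no filter (adjusted p = 0.147), and miR-146a-5p, detected on 2 of the 3 P5 arrays, with the authors' processed values (4.00, adjusted p = 0.134). miR-142-3p (0.91 ± 0.54) and miR-223-3p (0.74 ± 0.23) did not pass. The median of the list was 1.02, and it was 1.60 without P4 replicate 1 and 0.67 without P4 replicate 3 and 0.36 with no scaling. With normexp neither the leukocyte list (median 0.74, adjusted p = 0.0935) nor the skeletal muscle list (0.70, adjusted p = 0.108) was called, and the leukocyte list was not called on miRNAs detected on all 6 arrays (0.91, adjusted p = 0.0865). The 3 measured skeletal muscle miRNAs, miR-1a-3p, miR-133b-3p and miR-133a-3p, were detected on no P5 array and were at least 17.3-fold, 5.3-fold and 4.17-fold higher in P4 (camera adjusted p = 0.0028; adjusted p = 0.348 with an estimated correlation), while miR-206-3p was detected on no array. With normexp the 3 were at 1.51, 0.70 and 0.58, and with the authors' processed values at 9.97, 8.26 and 7.92. The list of fibroblasts and other mesenchyme had a median of 3.62 (1.92 with normexp). It passed camera (adjusted p = 4.7e-05), but not with an estimated correlation (adjusted p = 0.183). Of its 6 tested members 5 were higher, the miR-199, miR-143 and miR-145 members above. miR-152-3p, at 0.63 ± 0.20, did not pass (adjusted p = 0.0568), and miR-214-3p and miR-127-3p were detected on no array. miR-143 and miR-145 are also made by contractile cells such as myoepithelium, which P4 holds, so this call does not show mesenchyme. No erythroid miRNA could be tested, and miR-451a was detected on 4 of the 6 arrays.

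The arrays of each population differed among themselves in these markers. On the log2 scale, P4 replicate 3 lay above the P4 mean by 0.82 for the 2 miR-126 arms and by 0.78 for the 3 miR-199 miRNAs. The mean of the 6 leukocyte miRNAs lay above it there by 0.59. Replicate 1 lay at -0.53, -0.62 and -0.51 for these sets. Not all leukocyte miRNAs followed their mean: miR-223-3p (-2.20, -2.54 and -2.57 on P4 replicates 1, 2 and 3) and miR-146a-5p (-3.16, -2.92 and -3.24) lay lowest on replicate 3. The other leukocyte miRNAs lay highest there. For the cluster of miR-143 and miR-145 replicate 1 was at 0.39 and replicate 3 at -0.34, and for the skeletal muscle miRNAs these were 0.46 and -0.38. The miR-200 family was at 0.23 on replicate 1 and at -0.39 on replicate 3. Within P5 miR-126-3p varied more than within P4 (SD 0.857 against 0.728). P5 replicate 3 lay at -0.97 from the P5 mean for the 2 miR-126 arms, against 0.63 and 0.35 on replicates 1 and 2, while the leukocyte miRNAs lay between -0.17 and 0.13 and the miR-200 family between -0.16 and 0.12.

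**Figure D3:**
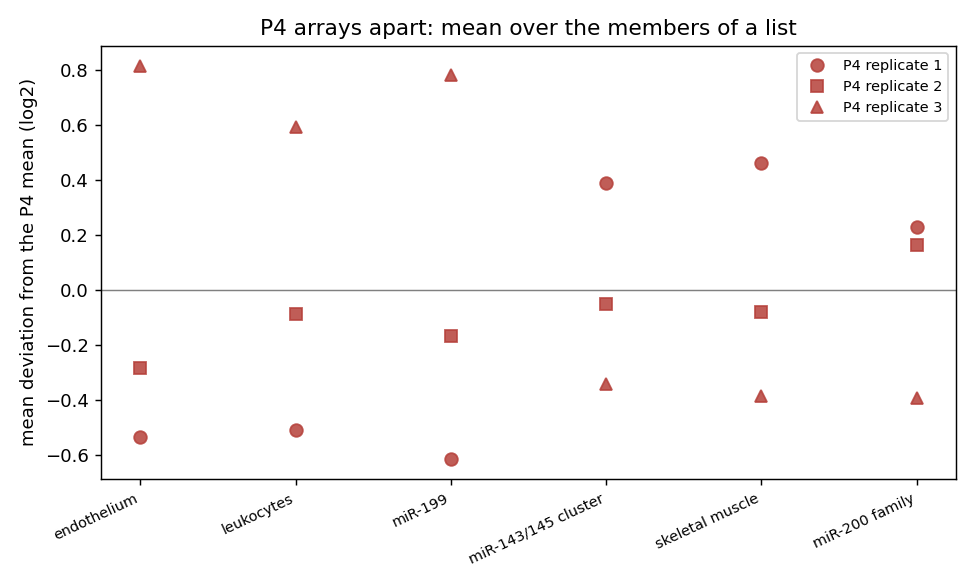
Mean deviation from the P4 mean on the log2 scale (vertical axis) of the members of 6 sets (horizontal axis) on each of the 3 P4 arrays, with no error shown. Replicate 3 is the highest for endothelium, leukocytes and miR-199 (0.82, 0.59 and 0.78), and replicate 1 for the cluster of miR-143 and miR-145 and skeletal muscle (0.39 and 0.46). Within the leukocyte set miR-223-3p and miR-146a-5p were lowest on replicate 3.

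The remaining lists were not called by camera. fry, which does not compare a list with other miRNAs, passed the 10 lists called by camera (adjusted p up to 0.0159) and also the family of miR-15 and miR-16 (fry adjusted p = 0.00118, camera adjusted p = 0.549). For a change in either direction it also passed the stratified and basal list (adjusted p = 0.000847) and the Dlk1-Dio3 imprinted region (adjusted p = 0.0328). The let-7 family had 1 of 9 members past the threshold, let-7b-5p (-0.60 ± 0.17), a call lost without P4 replicates 1, 2 or 3 or P5 replicates 1 or 3 (-0.50 to -0.66, adjusted p = 0.0615 to 0.110); none passed when adjusted over the list alone. let-7c-5p differed by -0.29 ± 0.17 (adjusted p = 0.234). In the cluster of miR-183, miR-96 and miR-182 miR-96-5p was lower (-0.70 ± 0.21), a call lost without P4 replicates 2 or 3 or P5 replicates 1 or 2 (-0.50 to -0.78, adjusted p = 0.0644 to 0.136), and miR-182-5p (-0.46 ± 0.21) did not pass. The call of miR-96-5p was also lost with normexp (-0.32, adjusted p = 0.255), Agilent's summed signal (adjusted p = 0.0581) and detection on 1 array as the filter (adjusted p = 0.0683). The family of miR-15 and miR-16 had 2 of 5 members higher, miR-497-5p (1.08 ± 0.20) and miR-195a-5p (0.91 ± 0.17), neither of which passed with no scaling (0.43 and 0.25) or the authors' processed values (0.76 and 0.58, adjusted p = 0.0646 and 0.0734). In the clusters of miR-193 and miR-365 1 of 3 was lower, miR-193b-3p (-1.22 ± 0.22), and in the Dlk1-Dio3 imprinted region 1 of 4 was higher, miR-370-3p (0.98 ± 0.18), while 29 of its 34 members on the array were detected nowhere. None of the tested members passed in the miR-29 family (3), the cluster of miR-322 and miR-503 (3) and the Sfmbt2 intron cluster (10), where miR-29a-3p was at -0.34 ± 0.24, miR-322-5p at -0.43 ± 0.41 and miR-466i-5p at -0.33 ± 0.23. Of the lists with fewer than 3 tested members, miR-10b-5p of the Hox clusters was higher (1.19 ± 0.28), a call lost without P5 replicate 2 (1.05, adjusted p = 0.0645), with the authors' processed values (0.86, adjusted p = 0.096) and with detection on 1 array as the filter (adjusted p = 0.0535). With the array row as a block let-7b-5p, miR-96-5p, miR-497-5p, miR-195a-5p, miR-370-3p and miR-10b-5p did not pass (adjusted p = 0.066 to 0.185), and with no filter neither these 6 nor miR-193b-3p did (adjusted p = 0.0771 to 0.298). With no scaling let-7b-5p, miR-96-5p and miR-193b-3p were at -1.25, -1.35 and -1.87. miR-193b-3p did not pass with normexp (-0.39, adjusted p = 0.185), nor miR-370-3p and miR-10b-5p with no scaling (0.33 and 0.53). miR-212-3p of the cluster of miR-132 and miR-212 (0.08 ± 0.17) and miR-290-5p of the pluripotency clusters (0.11 ± 0.20) did not pass.

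Other miRNAs chosen beforehand for their known roles in mammary or epithelial cells gave mixed results. miR-22-3p was higher in P4 (1.11 ± 0.23, adjusted p = 0.00979), but did not pass with no scaling (0.46) or the authors' processed values (0.79, adjusted p = 0.0638). miR-146b-5p (-1.38 ± 0.24, adjusted p = 0.00449) and miR-93-5p (-0.93 ± 0.20, adjusted p = 0.0118; -1.59 with no scaling) were lower. With the array row as a block miR-22-3p (0.96, adjusted p = 0.149) and miR-93-5p (-0.75, adjusted p = 0.164) did not pass, and with no filter neither these nor miR-146b-5p did (adjusted p = 0.115 to 0.154). miR-21a-5p, abundant in both populations, differed by -0.75 ± 0.30 and did not pass (adjusted p = 0.111), although it passed with 4 of the other settings. Close relatives such as miR-199a and miR-199b, miR-133a and miR-133b, or miR-204 and miR-211 share most of their sequence, and how far the probe of 1 reads the other was not tested. miR-199b-3p had no name of its own on the array, so its part in the value of miR-199a-3p is unknown.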

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

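Signals outside the comparison were found in Agilent's spike-in control probes, which the tests left out. The control probe dmr_285 was detected on 4 of the 6 arrays and the control probe dmr_6 on 2. Their summed signals were between 5.07 and 17.8 intensity units where detected. The control probes dmr_3, dmr_308, dmr_316 and dmr_31a were detected on no array. The file headers mark the labelling and hybridisation spike-in signals as out of range on all 6 arrays. No explanation was tested. Groups of 3 arrays are too small for the search for outlying arrays.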

How the results depend on the processing

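The array row block and the higher floor were chosen after the data were seen. No miRNA called with another setting went opposite to its call reported here. For the 52 named called miRNAs, 1034 of 1131 values under other settings kept direction and call, 96 kept direction only and 1 reversed: miR-32-5p, near the floor, was at 0.0462 with normexp. The other filters, the other eBayes setting and the replicate block leave each log2 difference as it is, so direction could not change there. The settings that leave out an array share most of their data. All 10 called lists lost their call with an estimated correlation. This held also for the fibroblast list, whose estimated correlation was negative (-0.115), so the loss can reflect more than correlation within lists. Under the other settings 211 of their 218 values kept both and 7 kept direction only. Causes were not tested except where the construction of the setting shows them.

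Of miRNAs differing between P4 and P5, 47 were called with no filter (25 higher, 22 lower), where 1247 were tested, and 52 with the array row as a block (29 and 23), which uses 1 P5 array. Higher calls numbered 23 with no scaling and 31 with the series matrix, where lower calls were 81; lower calls were 25 with normexp. Testing only miRNAs detected on all 6 arrays, which removes members, left 4 higher lists, and an estimated correlation left 0. Without each array in turn, 85 to 121 were called, 43 to 72 higher and 40 to 56 lower, with 10 to 11 lists, 7 higher and 3 to 4 lower. The group difference in miRNAs detected per array ranged from -58.5 to -24.7.

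Calls of lists changed as follows. With an estimated correlation none was called. The miR-30 family was not called with quantile normalization (median -0.53), no scaling (-1.15) or the series matrix (-0.82) or without P4 replicate 3 (-0.47), and ranged from -0.61 to -0.46 without each array. The leukocyte list was not called with normexp (0.74) or on miRNAs detected on all 6 arrays (0.91), nor the skeletal muscle list with normexp (0.70). The let-7 family was called with normexp (-0.33). Without each array the miR-29 family ranged from -0.70 to -0.31 and was called without P5 replicate 2, and the Sfmbt2 intron cluster ranged from -0.51 to -0.0571 and was called without P4 replicate 3.

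Reversals among miRNAs and lists that were not called were these. With all miRNAs scaled, miR-212-3p was at -0.0923 and miR-290-5p at -0.0563. With no scaling these were -0.58 and -0.54, miR-542-3p was at -0.39, and the stratified epithelium, miR-15 and miR-16, and Dlk1-Dio3 lists were at -0.16, -0.29 and -0.12. With the series matrix, miR-212-3p, miR-542-3p and miR-290-5p were at -0.25, -0.058 and -0.21. miR-212-3p was at -0.0133 with the median scaling, and miR-290-5p at -0.033 with quantile normalization. Without each array, miR-212-3p ranged from -0.0031 to 0.19 and miR-290-5p from -0.0865 to 0.23. With normexp, miR-669p-3p was at 0.26, miR-182-5p and the list of its cluster at 0.0221, the miR-322 and miR-503 list at 0.0143 and the Sfmbt2 intron cluster at 0.28.

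Whether the replicate numbers pair the samples cannot be settled with 3 arrays per group. Deviations of same-numbered arrays correlated at -0.07, 0.37 and 0.09, and those of differently numbered arrays at -0.42 to 0.22. With the replicate block 111 miRNAs were called, 101 of them shared with those reported. The slide block could not be run because all arrays share 1 slide. Signal over background limits the folds of miRNAs near the floor.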

Other observations

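All tests in this part except the count of calls in other splits of the arrays were chosen after the results were seen. So were the miRNAs of the next paragraph, except miR-146a-5p and miR-146b-5p.

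Further miRNAs outside the lists differed between P4 and P5. miR-338-3p, miR-218-5p and miR-139-5p were detected on all 3 P4 arrays and on no P5 array, and were at least 7.81-fold, 5.71-fold and 5.92-fold higher in P4. These bounds leave out the spread between arrays. The 95% intervals of their log2 differences from limma had lower ends at 2.58, 2.19 and 2.00. Both arms of miR-140, known from cartilage, were higher in P4 (1.35 ± 0.19 for miR-140-3p and 1.29 ± 0.16 for miR-140-5p). On the other side, miR-7a-5p and miR-362-3p were detected on all 3 P5 arrays and on no P4 array, and were at least 2.53-fold and 2.71-fold higher in P5. miR-425-5p (-1.15 ± 0.17) and its neighbour miR-191-5p (-0.74 ± 0.17) were both lower in P4. miR-146a-5p of the leukocyte list and the candidate miR-146b-5p, both given above, share a seed. They went opposite ways, by 2.03 ± 0.20 and -1.38 ± 0.24.

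The arms of a hairpin differed less from each other than shuffled pairs did. Over 38 pairs of arms the median absolute difference between their log2 differences was 0.474, against 1.04 in shuffled pairs (permutation p = 0.0003, 10000 shuffles). Over the 24 pairs detected on all 6 arrays it was 0.344 against 0.805 (permutation p = 0.0005). Detection did not keep every value off the floor: miR-3092-5p lay at it on P5 replicate 3. Of the 38 pairs 10 had opposite signs, and of the 9 with both arms called 0 had. Several called arms had a partner near 0: miR-211-5p, miR-338-3p and miR-139-5p, detected on no P5 array, were at least 23.2-fold, 7.81-fold and 5.92-fold higher in P4, beside miR-211-3p at -0.25, miR-338-5p at 0.01 and miR-139-3p at 0.04. Over 35 pairs of neighbouring miRNA genes, within 10000 bases in the GRCm38.p6 gene table, the value was 0.362 against 0.641 (permutation p = 0.0088), with opposite signs in 9 pairs and in 0 of the 12 with both called. Over the 24 of these pairs detected on all 6 arrays it was 0.334 against 0.614 (permutation p = 0.016). These medians are consistent with some control at the level of the hairpin or its transcript, not for each pair. Cross-reading between probes of similar members remains open for pairs of related sequence.

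Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many calls as the real one, which is the real split itself (103 calls), and the highest of the others gave 0. With 10 splits the share cannot fall under 0.05.

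Both arms of miR-126 and 2 of 6 leukocyte miRNAs were called higher in P4. Yet the lineage-negative gate is meant to remove blood and vessel cells. With no filter the miR-126 differences were unchanged, but their calls were lost (adjusted p = 0.146 and 0.150). The call of the leukocyte list was lost with an estimated correlation (adjusted p = 0.348), with normexp and on miRNAs detected on all 6 arrays. A lower share of epithelial cells would raise both lists alike only if each member were specific to its cell type and off the floor. miR-146a-5p lay at the floor on P5 replicate 3, and the leukocyte miRNAs differed unequally, from 0.47 (miR-155-5p) to 2.20 (miR-150-5p). The difference between the lists is thus no direct measure of a cell share. The endothelial minus the leukocyte mean was higher in P4 by 1.67 ± 0.55 (SE). That is beyond 2 SE, the bound first set, but the 95% interval allowing unequal spread, which replaced that bound after the value was seen, runs from -0.48 to 3.83 and includes 0; that this explanation stays open rests on that change. Vessel and blood cells in a share that varies between sorts may contribute, though the labels do not say whether the arrays hold separate sorts. Within P4 the median SD of 6 marker hairpins was 0.573, at percentile 99.98 of random sets matched on signal, and within P5 at percentile 85.6. Random sets do not share a cell type, so sets that vary together reach high percentiles easily. Expression of these miRNAs in P4 cells themselves was not tested.

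The 3 miR-199 miRNAs moved with miR-126 among the P4 arrays, which might mean that the same cells carry both. The SD of their log2 ratio to miR-126-3p was at a median percentile of 1.36 among miRNAs within P4. It was 15.5 within P5, but miR-199a-5p was detected on 1 P5 array and miR-199b-5p on 2, so that median cannot speak for or against shared cells. miR-199a-3p, detected on all 3 P5 arrays, was at percentile 20.4 there. It lay at -3.77, -3.47 and -3.76 on P5 replicates 1, 2 and 3, where miR-126-3p lay at 0.87, 0.60 and -0.73. That 1 miRNA did not move with miR-126 within P5. Within P4 the leukocyte miRNA miR-150-5p tracked miR-126-3p more closely (percentile 0.815) than any of the 3 miR-199 miRNAs did (1.09 to 5.98). The tracking of miR-199 was seen before the test was written, so it cannot establish that the same cells carry both. Mesenchymal cells with the miR-199a and miR-214 transcript stay open too, with miR-214-3p detected on 0 arrays, although the gate for CD24-positive cells is meant to leave out stroma. These explanations cannot be told apart here.

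The muscle miRNAs miR-1a, miR-133a and miR-133b, higher in P4, moved with miR-143 among the P4 arrays. The SD of their log2 ratio to miR-143-3p was at a median percentile of 2.45 among miRNAs, which could fit production in the same contractile cells. It was seen before it was tested, miR-205-5p tracked miR-143-3p as closely (percentile 1.90), and the 3 muscle miRNAs were measured on 3 arrays alone. Skeletal muscle fibres, which a sort of single CD24-positive cells is meant to remove, might also bring them if carried over: miR-206-3p, a miRNA of skeletal muscle, was detected on 0 P4 arrays, but it can lie below detection when miR-1a is weak. These explanations cannot be told apart here.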
